A study of Homo sapiens with 18 samples.

How the data were processed

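ChIP-seq for H3K4me1, H3K4me3 and H3K27ac had been done in MCFDCIS and MCFDCIS-D4 cells, in 16 ChIP libraries, with 1 input library per line. Per the labels' protocols, chromatin was crosslinked with formaldehyde and sonicated, and libraries were made from the purified DNA fragments. Per the labels, 1 list of regions stands for all libraries of a line and mark, set against the input of the line. The series text speaks of triplicates, and the labels name 2 parental libraries for H3K4me1 and for H3K4me3. The genome build was hg19, per the submitters' processing notes. The aligner and the peak caller are not given in the sources used here.

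Each of the 6 files lists the chromosome, start and end of regions and a score. The score in the deposited lists is the authors' value for each region and its scale is not stated. Every score lay above 10, and the median H3K4me3 score was 193 in parental and 77.9 in D4, so scores were used only to rank and filter regions within 1 list. Regions lie on a grid of 1 kb and are 1 to 10 kb wide. All 39973 regions lie inside the chromosomes of GRCh37. The lists hold regions on 20 chromosomes, with none on chromosomes 20, 21, 22 or Y, and genes on these were not analysed here. The files hold no value per library, so replicates could not be compared, no count test was made and the depth behind a region is unknown. A region that is absent from a list may have lain just below the authors' threshold.

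Samples were grouped by line and mark from the labels, and D4 was compared with parental within each mark. Regions were called shared when they overlapped a region of the other line by at least 1 bp, and listed in D4 only or in parental only otherwise. The share expected by chance came from 100 random placements of the regions on their own chromosome. Intervals of shares are 95% Wilson intervals. They describe the number of regions, not replicates. The annotation was GENCODE 44 mapped to GRCh37, with 18547 protein-coding genes on the chromosomes in the lists. A promoter was 1 kb on each side of any TSS of a protein-coding transcript. Other regions were distal and, where the nearest TSS lay within 50 kb, were assigned to its gene.

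The 22 gene lists with 412 entries, the comparisons, the alternatives and the rule for the genes named were fixed before the data were examined. Of the entries, 385 matched the annotation, 1 of them through an older symbol from a table of RefSeq genes on GRCh38.p14 that was used for names only. For each list and mark, the number of promoters marked in D4 only minus the number marked in parental only was set among 10000 random gene lists with as many genes marked in the parental line, and given as a percentile with ties counted as 50%. Percentiles describe these lists and are not p-values. Over 66 combinations of list and mark, some lie outside the middle 95%, percentiles 2.5 to 97.5, by chance. Random lists matched also on parental H3K4me3 were added after the data were seen. Distal regions were treated in the same way with random lists of the same size.

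The rule named, per mark, the 10 promoter regions with the highest score listed in D4 only and the 10 in parental only, the 5 and 5 distal regions likewise, every list member whose promoter differed in 2 or more marks in the same direction, and NCOA3. Other names are members of the fixed lists or are said to have been chosen after their values were seen. Motif matches on both strands were counted in distal H3K27ac regions and in 10 dinucleotide shuffles of each sequence, with exact Poisson intervals. Chromosome arms were divided at the longest run of unknown bases. Zinc finger genes were those whose symbol is ZNF and a number, with or without letters after it. The comparison of regions and the percentiles of promoter gene lists were tested on simulated data, and the other procedures were not: of 200 regions removed from or added to the H3K27ac list, 200 and 200 were found, and of 200 random lists 3 lay above percentile 97.5. Alternatives were the 50% of each list with the highest score, lists of equal length, autosomes only, other overlap rules, merged regions and other promoter definitions. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, matplotlib 3.10.9 and samtools 1.23.1 were used.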

Results

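The series profiled 3 histone marks by chromatin immunoprecipitation and sequencing (ChIP-seq) in 2 human cell lines. MCFDCIS is a line of breast ductal carcinoma in situ, a lesion whose cells still lie within the milk duct, and is called the parental line here. MCFDCIS-D4, called D4, carries the genotype label AIB1 delta4. AIB1, encoded by NCOA3, is a coactivator of nuclear receptors, and the delta4 isoform lacks exon 4. The marks were H3K4me1, found at enhancers, H3K4me3, found at promoters, and H3K27ac, found at active promoters and enhancers. H3K4me1 and H3K4me3 had 2 parental and 3 D4 libraries each, H3K27ac had 3 libraries in each line, and each line had 1 input library. The 6 files hold 1 pooled list of enriched regions per line and mark, so each line has 1 value for every quantity. The differences between the lines therefore have no replicate check, no p-value is given for any region, gene or gene list, and the sequencing depth of the libraries is unknown. Coordinates are 1-based on human build hg19.

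Of the 3 marks, H3K27ac had the largest ratio of region numbers between the lines. D4 listed 8798 H3K27ac regions and the parental line 5035, a ratio of 1.75, and the covered length was 14.6 Mb against 7.16 Mb. Away from promoters the ratio was larger, with 2460 D4 regions against 979 parental ones, a ratio of 2.51. Promoter regions numbered 6338 against 4056, a ratio of 1.56. H3K4me3 had 12322 regions in D4 and 11385 in parental, a ratio of 1.08, which was 1.03 at promoters and 1.51 away from them. H3K4me1 gave short lists of 1435 and 998 regions, a ratio of 1.44.

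Of the D4 H3K27ac regions, 51.5% overlapped a parental region (95% Wilson interval 50.4% to 52.5%), which left 4270 listed in D4 only. Of the parental H3K27ac regions, 90.4% overlapped a D4 region and 484 were listed in the parental line only. For H3K4me3 the shared part was 90.3% of the D4 list and 97.9% of the parental list, with 1190 regions in D4 only and 241 in parental only. For H3K4me1 it was 20.7% and 30.1%, with 1138 and 698 regions in 1 line only. Random placement of the regions on their own chromosomes gave a mean overlap of at most 1.60% in any of these comparisons. H3K27ac regions that matched 1 to 1 were wider in D4 at 37.3% of 4475 places and narrower at 3.67%, those of H3K4me3 at 24.3% and 3.71% of 11091 places and those of H3K4me1 at 38.5% and 19.4% of 288. The excess of D4-only over parental-only regions depends on the length of the lists, and lists of equal length give nearly equal numbers by construction. With both H3K27ac lists taken at 5035 regions by score, 1665 were listed in D4 only and 1646 in parental only.

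**Figure D1:**
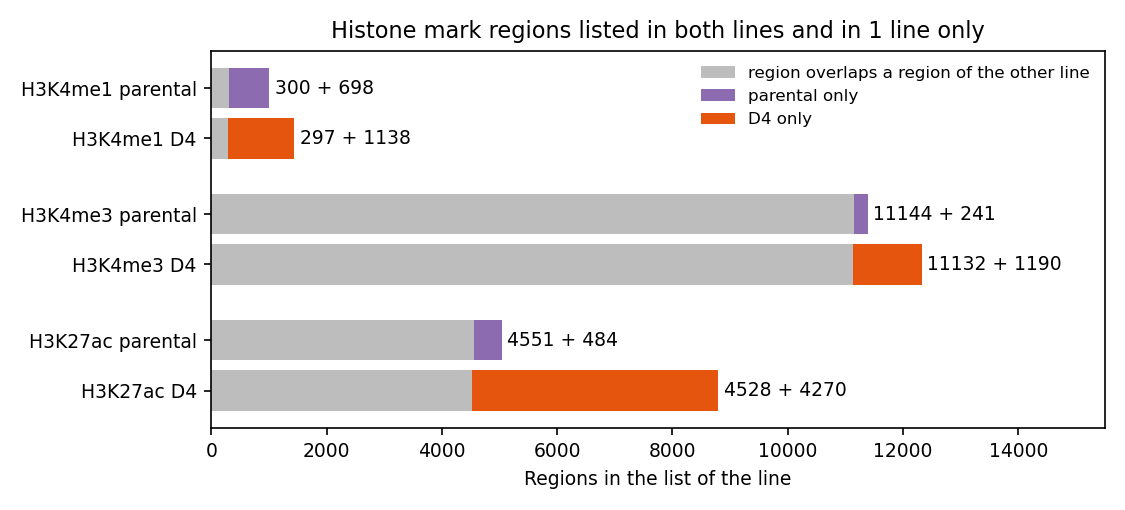
Number of regions in each list, by mark and line. Grey bars are regions that overlap a region of the other line by at least 1 bp and coloured bars are regions listed in that line only. The numbers give both parts, such as 4528 shared and 4270 D4-only H3K27ac regions in D4.

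At promoters, defined as 1 kb on each side of a transcription start site (TSS) of a protein-coding gene, H3K27ac marked 7097 of 18547 genes in D4 and 4652 in parental. It was present in D4 only at 2636 genes, in parental only at 191 genes and in both lines at 4461 genes. Of the 2636 genes with H3K27ac in D4 only, 97.7% carried H3K4me3 in the parental line, as did 96.9% of the 191 and 99.6% of the 4461. Among all 4270 D4-only H3K27ac regions, promoter or not, 59.4% lay on a parental H3K4me3 region.

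Genes of epithelial cell junctions were marked more often in D4. Of the 20 genes of this group, 8 carried promoter H3K27ac in D4 only, none in parental only and 7 in both. The 8 were CLDN1, CLDN4 and CLDN7, claudins of the tight junction, DSG3 and JUP of the desmosome, the adhesion molecule EPCAM, the epithelial transcription factor GRHL2 and the membrane protease ST14. The excess of 8 lay at percentile 100.0 of 10000 random gene lists with the same parental H3K27ac state, and at percentile 97.5, just inside the middle 95%, when the random lists also had the same parental H3K4me3 state, a match added after the data were seen. The CLDN7 region (chromosome 17, 7164001 to 7166000) had a score at percentile 81.5 of the D4 list and the ST14 region (chromosome 11, 130029001 to 130030000) one at percentile 3.30. The DSG3 region overlapped in part a parental region outside the promoter. With both lists taken at 5035 regions, 3 junction genes were marked in D4 only and 1 in parental only, at percentile 93.9, and in the 50% of each list with the highest score 4 and 1 were, at percentile 86.4.

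The mesenchymal and EMT group went the other way. Of its 19 genes, 3 carried promoter H3K27ac in parental only and 1 in D4 only. Random lists, most of whose differing genes were marked in D4, averaged 1.54 more D4-only than parental-only genes, and the difference of -2 lay at percentile 0.40, or 0.095 with the H3K4me3 match. The parental-only genes were FOXC2, a transcription factor of mesenchymal tissues (chromosome 16, 86600001 to 86602000, score percentile 53.4 in the parental list), S100A4 (chromosome 1, 153521001 to 153522000, percentile 3.16) and TGFBI, a matrix protein induced by TGF-beta (chromosome 5, 135365001 to 135370000, percentile 3.60). At TGFBI a D4 region still overlapped the parental one, away from the start site. The D4-only gene was TGFB1. With lists of equal length the difference was -6, at percentile 0.205, and in the 50% of each list with the highest score it was -1, at percentile 3.89.

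Inflammatory cytokine and NF-kB genes were marked more often in D4. Of 19 genes, 7 carried promoter H3K27ac in D4 only and none in parental only, at percentile 99.3, or 100.0 with the H3K4me3 match. They were the chemokines CCL20 and CXCL3, the cytokines CSF2 and IL24, the prostaglandin synthase PTGS2, and NFKB2 and RELB, subunits of the non-canonical NF-kB pathway. CCL20 had a 7 kb region (chromosome 2, 228678001 to 228685000) with a score at percentile 97.2 of the D4 list, part of which overlapped a parental region outside the promoter. With only the most 5′ TSS of each gene the excess was 5, at percentile 94.6. Basal and myoepithelial breast genes had 5 of 20 members in D4 only and none in parental only, at percentile 95.7, with 97.9 under the H3K4me3 match and 88.1 with the most 5′ TSS only. Among these were ACTA2, the hemidesmosome collagen COL17A1 and the integrin ITGA6, whose region overlapped in part a parental region outside the promoter. The ACTA2 region (chromosome 10, 90750001 to 90752000) counted because it lay at any 1 annotated start site of the gene. Whether that start site is the one used in myoepithelial cells was not tested.

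Among groups tied to AIB1 and its partners, nuclear receptor coactivators had 3 of 12 promoters marked in D4 only (HDAC3, MED1 and NCOA1), at percentile 99.1, or 92.8 with the H3K4me3 match. NCOA3 itself lies on chromosome 20, where no list has a region, and was not analysed here. YAP/TEAD targets had 2 D4-only genes, AXL and RBMS3, and 1 parental-only gene, TGFB2, of 23, at percentile 59.6. The Hippo pathway core had 3 of 17 in D4 only, at percentile 94.1, or 76.1 with the H3K4me3 match. Housekeeping genes had 4 of 20 in D4 only, at percentile 98.2, or 92.8 with the match, and cell cycle genes 4 of 20, at percentile 96.9, or 78.9 with the match. HOX genes had 8 of 39, at percentile 83.6. Glucocorticoid targets had SGK1 in D4 only and KLF9 and ZBTB16 in parental only, at percentile 9.14. Matrix proteases, luminal breast, interferon, Notch and Wnt, AP-1, stem cell, and EGF, ERBB and IGF genes lay between percentiles 11.4 and 93.1. The 15 blood cell genes and the 19 silent tissue-restricted genes carried promoter H3K27ac in neither line, at percentiles 2.13 and 1.08, and 1 of 10 fibroblast genes (FAP) was marked in parental only, at percentile 0.295. With the H3K4me3 match these lists lay at percentiles 27.04, 42.4 and 4.29. Of the 8 endothelial genes, 1 was marked in both lines, at percentile 12.9.

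**Figure D2:**
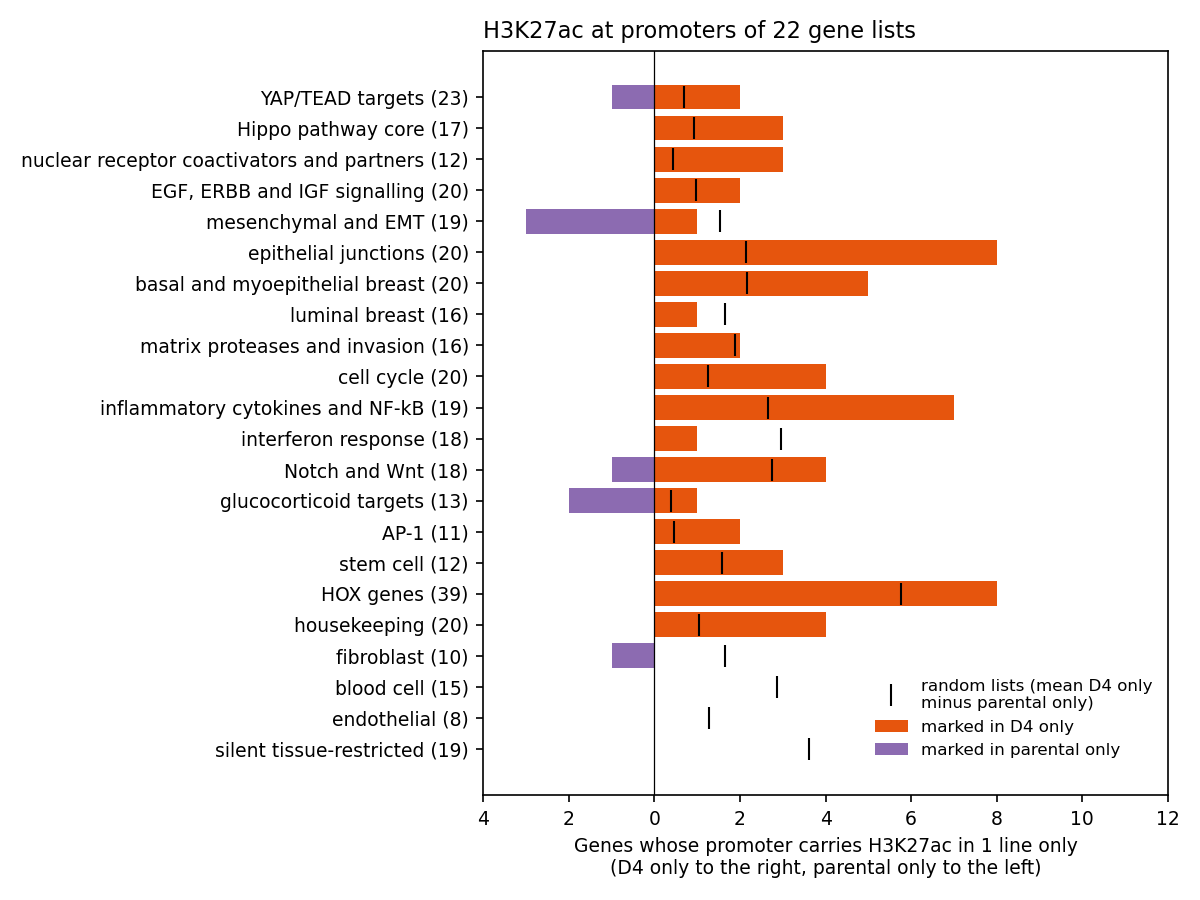
Genes of 22 lists, with the number of members in brackets, whose promoter carried H3K27ac in 1 line only. Orange bars to the right count D4-only genes, purple bars to the left parental-only genes, and black ticks mark the mean difference of 10000 random lists. Epithelial junctions reach 8 D4-only genes, and mesenchymal and EMT genes have 3 parental-only genes against 1.

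The D4-only H3K27ac promoter regions with the highest scores lay at MFN2, a mitochondrial fusion protein, the small GTPase gene RHOG, SLC2A1, the glucose transporter GLUT1, MPG, UBE2H, CYFIP1, NUP98, TRNP1, RNF207 and INTS3, all above percentile 99.2 of the D4 list. The SLC2A1 region spanned 43424001 to 43425000 on chromosome 1 and covered exonic sequence at the start of the gene. In parental only they lay at TMEM70, the monocarboxylate transporter SLC16A5, ZC3H12C, LCOR, a nuclear receptor corepressor, NQO1, a quinone reductase induced by oxidative stress, KLF7, SRRT, ANKRD12, AGFG1 and TK2, between percentiles 78.1 and 94.6 of the parental list. At SLC16A5, NQO1 and SRRT a D4 region began directly beside the parental one.

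Distal H3K27ac regions, outside promoters and with the nearest TSS within 50 kb, were assigned to that gene. EGF, ERBB and IGF signalling genes had distal D4-only regions at 8 of 20 members, among them the ligands AREG, EREG and TGFA and the receptors EGFR and IGF1R. EGFR and IGF1R also had parental-only regions. Basal and myoepithelial genes had them at 7 of 20, among them TP63, the master regulator of basal cells, CAV1, ITGA6, ITGB4 and SFN, with none in parental only. AP-1 genes had them at 4 of 11, which were FOS, JUN, FOSL2 and ATF3, and the Hippo core at 3 of 17, which were YAP1, WWTR1 and TEAD1. YAP/TEAD targets had 4 D4-only and 1 parental-only gene. Of the 19 mesenchymal and EMT genes, 4 had distal D4-only regions, VIM and SPARC among them, in contrast to that group's promoters. Inflammatory and NF-kB genes had 5 genes with D4-only regions, of which BIRC3 also had a parental-only region, and Notch and Wnt genes 4 and none. These groups lay at percentiles 93.9 to 100.0 of random lists that were matched on size alone, so genes in active use were not set apart. The other lists lay between percentiles 10.7, for HOX genes, and 95.65, for epithelial junctions, with housekeeping genes at 21.1, cell cycle genes at 21.6, matrix proteases at 25.1 and nuclear receptor coactivators at 30.0. The highest scoring distal regions lay near KIF6, IRX4, SMIM2, CD9 and PLCD3 in D4 only and near MTHFD1L, ASAP1, CAB39, GAS6 and C8orf74 in parental only. A D4 region lay directly beside the parental-only region near CAB39.

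AP-1 sites (TGASTCA) occurred at 0.421 per kb in the 1763 distal D4-only H3K27ac regions (95% exact Poisson interval 0.396 to 0.447), at 0.346 per kb (0.319 to 0.375) in the 697 distal shared regions and at 0.369 per kb (0.302 to 0.447) in the 240 distal parental-only regions. The same sequences with their dinucleotides shuffled held 0.177, 0.168 and 0.190 per kb. TEAD sites (WGGAATGY) occurred at 0.235 (0.216 to 0.255), 0.222 (0.20 to 0.245) and 0.307 (0.246 to 0.378) per kb in the same order, against 0.171, 0.161 and 0.190 after shuffling. The D4-only regions thus held 1.22 times the AP-1 density of the shared ones and 1.06 times their TEAD density. The share of regions with a site ran the other way, at 42.9% against 51.4% for AP-1 and 26.5% against 35.7% for TEAD, with 2449 kb in the D4-only regions and 1729 kb in the fewer and wider shared ones. In the middle 500 bp the intervals of the AP-1 density overlapped, with 0.478 per kb (0.433 to 0.525) in D4-only, 0.419 per kb (0.354 to 0.493) in shared and 0.500 per kb (0.382 to 0.644) in parental-only regions. The intervals cover counting error only.

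H3K4me3 marked 11458 gene promoters in D4 and 11177 in parental, with 11057 in both, 401 in D4 only and 120 in parental only. The D4-only promoters with the highest scores were CCND2, which encodes cyclin D2 (chromosome 12, 4380001 to 4385000, score percentile 59.7 of the D4 list), RNF212, the neuropeptide Y receptor gene NPY1R, the potassium channel genes KCNH2 and KCNH5, TSPAN12, ZNF699, IFITM10, NRTN and H4C11. No D4-only region was among the 25% of the D4 H3K4me3 list with the highest scores, and 1097 of the 1190 were among the 25% with the lowest. In parental only, the highest were ZBTB16, a zinc finger transcription factor induced by glucocorticoid (chromosome 11, 113930001 to 113933000, percentile 88.6 of the parental list), ZNF331, ZNF823, a gene model that shares its promoter with ZNF700, TENT5B, NOTCH3, an unnamed gene model at 23456001 to 23457000 of chromosome 19, SLC16A5, NKAIN3 and ZNF724. Of the fixed lists, basal and myoepithelial genes lay outside the middle 95% of random lists, with COL17A1 and TP63 in D4 only, at percentile 97.6, and no list lay outside it with promoters of 2.5 kb on each side. Glucocorticoid targets had distal D4-only H3K4me3 regions at 5 of 13 genes, DUSP1, FKBP5, GADD45B, KLF9 and PER1, and none in parental only, at percentile 100.0. Stem cell genes had them at 3 of 12 (ALDH1A3, ITGB1 and SOX2) and none in parental only, at percentile 99.8, and the other lists lay inside the middle 95%. The random lists for distal regions were matched on size alone, so genes with marked promoters were not set apart. Of the 13 glucocorticoid targets, 12 carried promoter H3K4me3 in both lines, while 60.3% of all genes carried it in parental. The distal regions with the highest scores were near PILRB, IFT22, TET1, OR10AD1 and GPSM1 in D4 only and near ZNF823, INSR, FAM156B, PSRC1 and DENND3 in parental only.

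Zinc finger genes made up a large part of the H3K4me3 promoters marked in parental only, a group chosen after the regions had been seen. They were 32 of the 120 genes, or 26.7%, against 3.16% of all parental H3K4me3 promoters. Random choice of 120 marked promoters gave a mean of 3.79 zinc finger genes and at most 14 in 10000 draws. Of the 32 genes, 27 lie on chromosome 19. Among the 401 promoters marked in D4 only, 12 were zinc finger genes. With lists of equal length 37 zinc finger genes were marked in parental only, or 15.0% of the 247 genes, and 9 in D4 only. In the 50% of each list with the highest score the numbers were 36 and 42, so the excess over D4 was absent there, and the 36 were 4.48% of the parental-only genes against 2.28% of all parental promoters. Between 11.81 and 12.51 Mb of chromosome 19, 8 neighbouring parental H3K4me3 regions in a row had no D4 region, 7 of them at ZNF823, ZNF441, ZNF440, ZNF700, ZNF136, ZNF44 and ZNF799. The longest such row in 1000 shuffles of the parental-only regions was 4.

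**Figure D3:**
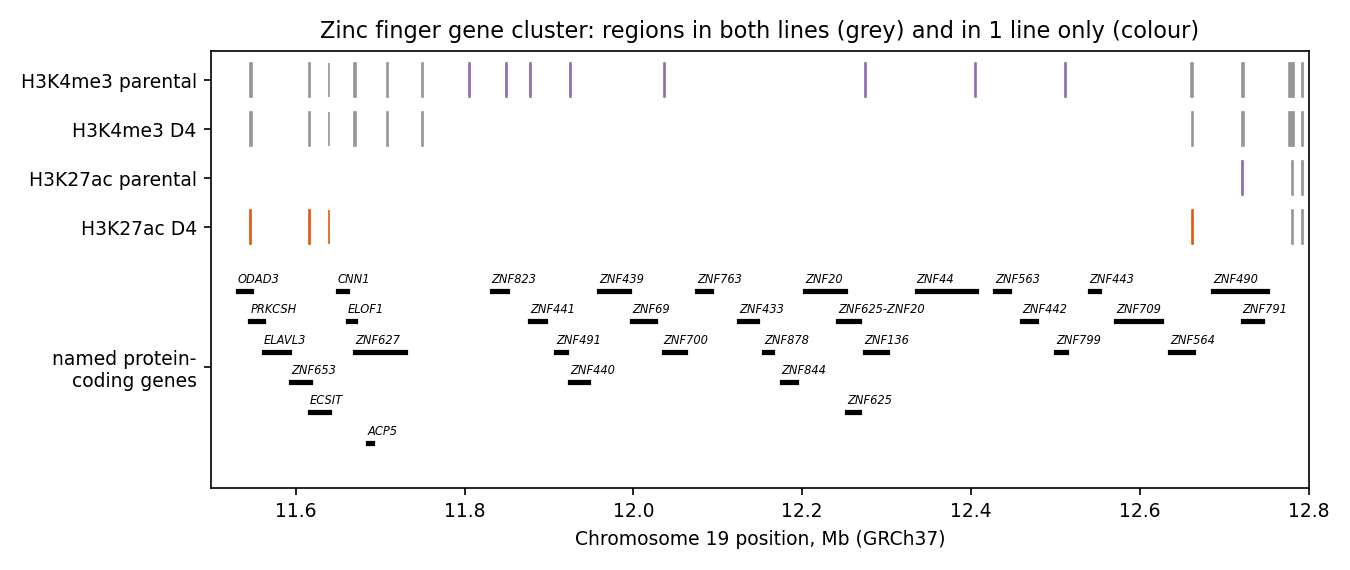
Map of 11.5 to 12.8 Mb of chromosome 19 (GRCh37) with the H3K4me3 and H3K27ac regions of both lines, drawn to scale, and named protein-coding genes as black bars. Grey regions overlap a region of the other line, purple ones are listed in parental only and orange ones in D4 only. The 8 purple H3K4me3 regions lie side by side, and the 10 others of the parental line have a D4 region.

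H3K4me1 lists were short and shared little, and only 18.2% of the parental and 18.3% of the D4 regions lay at promoters. The D4-only promoter regions with the highest scores were at FXYD5, LTBP3, DUSP2, NR2F6, SLC16A3, DNAJB5, SPTBN5, TMEM79, RIN1 and FGF1. Those in parental only were at ADGRG1, an intronic start site of EGFR, CCDC85C, RMDN3, CIRBP, SLC16A5, GCHFR, VSIR, the retinoic acid receptor gene RARA and LTBP3. The FGF1 and CCDC85C regions had a region of the other line directly beside them. LTBP3 had promoter regions in both lines, and the D4-only and the parental-only region lay 1 kb apart. Distal D4-only regions led near RXRA, SPSB1, SRSF5, ADSS1 and NTN3, and parental-only ones near SFRP1, a secreted Wnt inhibitor, HMGA1, MBNL2, TOM1L2 and MARK2. Promoters of 177 genes were marked in D4 only and of 110 in parental only, and with lists of equal length, which brings the numbers close by construction, they were 121 and 127. No fixed list lay outside the middle 95% of random lists at H3K4me1 promoters. YAP/TEAD targets had distal D4-only H3K4me1 regions at 6 of 23 genes (AMOTL2, ARHGEF17, AXL, CRIM1, NUAK2 and WWC1), and 3 of these 6 also had parental-only regions, at percentile 99.2. EGF, ERBB and IGF genes had them at 3 of 20 (ERBB2, HBEGF and TGFA) and none in parental only, at percentile 99.5, and the other lists lay inside the middle 95%. The random lists here were matched on size alone, not on chromosome arm. H3K4me1 regions were concentrated on a few arms that differed between the lines, so the location of the genes was not set apart.

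H3K4me1 regions were concentrated on a few chromosome arms that differed between the lines. In D4, arms 1q, 2p, 17q, 3q and 5q held 57.9% of them and 19.2% of the genes, and in parental 5q, 19q, 17q, 8q and 1q held 48.4% with 20.3% of the genes. Arm 3q had 152 regions in D4 and 28 in parental, 2p had 174 and 46, and 1q had 206 and 62. In the opposite direction, 5q had 144 in D4 and 200 in parental, and 8q had 35 and 65. The D4 over parental ratio of a whole chromosome lay more than 1.5 times from that of the genome on 14 of 20 chromosomes for H3K4me1 and on none for H3K4me3 or H3K27ac. The 14 include chromosomes with few H3K4me1 regions, such as chromosome 4 with 10 in D4 and 11 in parental, and 18 with 4 and 6. For H3K27ac, chromosome X lay just inside this limit, at 1.496 times the ratio of the genome. Its arm Xq had 56 H3K27ac regions in D4 and 14 in parental.

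**Figure D4:**
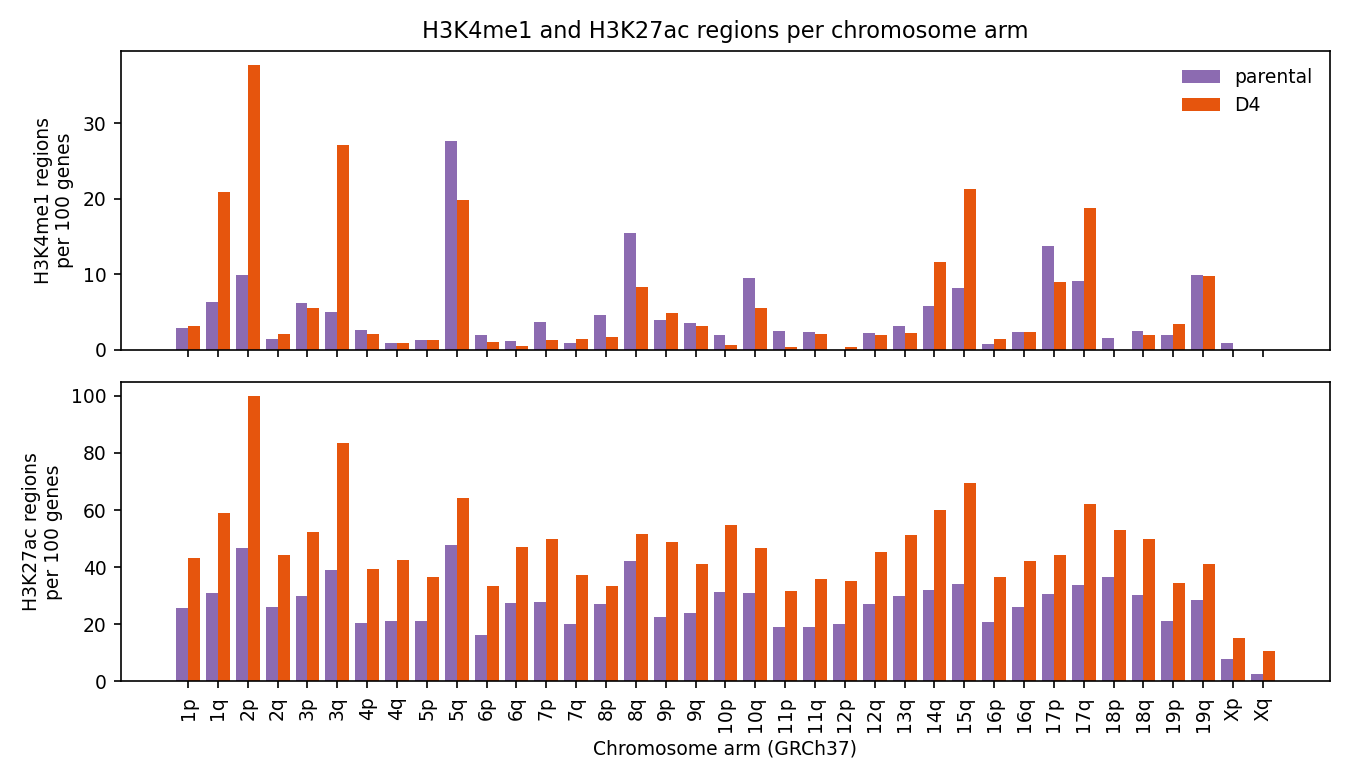
Regions per 100 protein-coding genes on each chromosome arm, for H3K4me1 above and H3K27ac below, with parental in purple and D4 in orange. H3K4me1 in D4 peaks on 2p at 37.7 and on 3q at 27.1 regions per 100 genes, against 9.98 and 4.99 in parental.

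Most H3K27ac regions lay on H3K4me3 of the same line. The share with H3K4me3 was 84.2% in parental and 76.4% in D4, and the share with neither H3K4me3 nor H3K4me1 was 12.6% (95% Wilson interval 11.7% to 13.5%) and 19.04% (18.2% to 19.9%). The H3K4me1 lists were short, with 998 and 1435 regions, and only 3.24% and 4.51% of H3K27ac regions lay on H3K4me1 alone. Most regions without H3K4me3 thus counted as having neither mark, which does not show that they lack H3K4me1. H3K4me3 regions that carried H3K27ac were 37.1% of the parental and 54.3% of the D4 list, and H3K4me1 regions that carried it were 22.04% and 35.9%. The H3K27ac list covered 14.6 Mb in D4 and 7.16 Mb in parental, and a longer list overlaps more of any other list. These 2 shares were not computed at equal list length. Of the listed genes, CCL20 and COL17A1 were marked in D4 only by H3K4me3 and H3K27ac and TGFB1 by H3K4me1 and H3K27ac. Both CCL20 regions overlapped in part a parental region of the same mark outside the promoter. In the other direction, NOTCH3 was marked in parental only by H3K4me1 and H3K4me3 and ZBTB16 by H3K4me3 and H3K27ac. Over all genes, SEMA3B, a secreted semaphorin, was marked in D4 only by all 3 marks and CD300A, an inhibitory receptor of blood cells, in parental only by all 3, both named after their values were seen.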

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

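Of the alternatives in this part, the random lists matched also on H3K4me3 were chosen after the data were seen and the others before. With both lists taken at the length of the shorter, the D4 over parental ratio of region number is 1.0 for all 3 marks by construction, which also brings the numbers in 1 line only close together. The shared share of the D4 list was then 23.6% for H3K4me1, 95.1% for H3K4me3 and 66.9% for H3K27ac. D4-only regions were 556 for H3K4me3 and 1665 for H3K27ac. Promoters in D4 only and parental only were 121 and 127 for H3K4me1, where the direction turned, 261 and 247 for H3K4me3, and 1353 and 1162 for H3K27ac. In the 50% of each list with the highest score, which removes regions by construction, the shared shares were 17.5%, 80.2% and 44.7%, and D4-only regions were 592 for H3K4me1 and 2434 for H3K27ac. Promoters were then 105 in D4 only and 50 in parental only for H3K4me1, 1224 and 803 for H3K4me3, and 504 in parental only for H3K27ac, and 80.4% of parental H3K27ac regions carried H3K4me3. With regions within 1 kb counted as shared, 23.3% of D4 H3K4me1 regions were shared. With only the most 5′ TSS, H3K4me1 promoters were 106 and 68. The number of lists outside the middle 95% of random lists was 0 for H3K4me1, 1 for H3K4me3 and 8 for H3K27ac. It was 1 for H3K4me1 and 0 for H3K4me3 in the 50% with the highest score, 2 for H3K4me3 at equal length (inflammatory and fibroblast genes), 0 for H3K4me3 with promoters of 2.5 kb, and 2 for H3K4me3 (Hippo core and housekeeping genes) and 4 for H3K27ac with the most 5′ TSS. The basal list, the 1 outside for H3K4me3, was thus inside in these 4 settings. It was 3 for H3K27ac with the H3K4me3 match, which were mesenchymal and EMT, basal and inflammatory genes. By covered length, 1 chromosome in place of none lay over 1.5 times from the genome for H3K27ac. The cause of the changes not due to construction was not tested. The other 68 values of these results, under autosomes only, merged regions, overlap of at least 50% of the shorter region, the middle 500 bp and the settings above, stayed within their interval or within 1.5 times. For the gene lists this compares numbers of lists, not their members: in the 50% with the highest score 7 lists lay outside for H3K27ac, of which inflammatory, housekeeping and fibroblast genes were also among the 8, while mesenchymal and EMT, epithelial junction, coactivator, blood cell and silent genes were not outside. The Hippo core, EGF, ERBB and IGF, basal and cell cycle lists lay outside only there among these 2 settings. At equal length 6 lists lay outside for H3K27ac. They were the Hippo core, coactivators, mesenchymal and EMT, cell cycle, inflammatory and housekeeping genes. No paired analysis was possible because each list pools its libraries. For the same reason, leaving out replicates, a replicate block, other size factors and a filter on low counts were not run. Depth is unknown, so it limits every list to an extent that cannot be given.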

Other observations

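The tests on copy number, gene density, the threshold of the parental list, random choice, segment loss and short deletions were chosen, or given their present form, after their patterns had been seen. The set of 31 arms and the genes in this part were also chosen after their values were seen.

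H3K27ac regions of both lines within 10 kb were joined into 7945 clusters, of which 5181 held more H3K27ac in D4 and 471 more in parental. An excess in this direction follows from the longer D4 list, which covered 14.6 Mb against 7.16 Mb. No count was made at equal list length. Some of those with the largest differences are given here. A cluster over ACTN4, an actin crosslinker (chromosome 19, 39138001 to 39213000), held 10 kb of H3K27ac in parental and 37 kb in D4. One with CAMK1G as the nearest gene held 18 and 43 kb, and one at C1orf116 and PFKFB2 held 4 and 24 kb. One at SDC1, a cell surface proteoglycan (chromosome 2, 20406001 to 20437000), held 6 and 23 kb, one at ACTN1 (chromosome 14, 69407001 to 69447000) 6 and 21 kb, and one at WWTR1, the gene of the Hippo effector TAZ (chromosome 3, 149290001 to 149308000), 1 and 16 kb. A cluster with THBS1 as the nearest gene held 6 and 19 kb, and clusters at LMNA and ITGA3 held 6 and 18 kb and 15 and 26 kb. In the other direction, a cluster with SEC22B as the nearest gene held 10 kb in parental and none in D4, one at VSIR 10 and 4 kb, and one at ZNF595 6 kb and none. No shared function of these genes was tested. The CAMK1G, C1orf116 and LMNA clusters lie on arm 1q, the SDC1 cluster on 2p and the WWTR1 cluster on 3q. On these arms D4 listed 3.32, 3.78 and 5.43 times as many H3K4me1 regions as parental. The ACTN4 cluster lies on 19q, with 80 H3K4me1 regions in D4 and 81 in parental. The SEC22B cluster, with more in parental, also lies on 1q. A link of the clusters with chromosome arm or copy number was not tested.

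H3K4me3 also had rows of neighbouring regions listed in D4 only. They included 4 spread over 4.405 Mb of chromosome 3 (89156001 to 93561000), with EPHA3 as the only gene whose promoter they marked. Others were 3 at the protocadherin alpha genes (chromosome 5, 140207001 to 140256000), 3 at the protocadherin beta genes (140501001 to 140604000), and 3 at FKBP5 (chromosome 6, 35695001 to 35745000). The longest row in D4 had 5 regions, and shuffles of the D4-only regions reached 6.

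D4 listed more H3K27ac regions than parental. If D4 libraries were only more sensitive, the extra regions would be the weakest of the D4 list. Of the 25% of D4 regions with the highest score, 22.3% had no parental region, against 78.7% of the 25% with the lowest score. This lies between the under 5% and over 40% set beforehand, so more sensitive detection and a change in acetylation cannot be told apart, since the files hold no depth and no value per library. An effect of the AIB1 isoform on H3K27ac is a candidate explanation that was not tested.

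H3K4me1 regions lay in a few segments that differed between the lines. Gene density argues poorly for the segments, since the variance-to-mean ratio of the region numbers per arm around those expected from start sites was 54.3 in D4 and 31.2 in parental, against 6.70 and 5.77 for H3K4me3 and 25.2 and 13.7 for H3K27ac. Copy number differences between the lines may contribute: across all 37 arms the D4 over parental ratio of H3K4me1 followed that of H3K27ac with Spearman's rho of 0.43 (permutation p = 0.0076, adjusted p = 0.011 over 6 relations) and Pearson's r of 0.32 (permutation p = 0.054, adjusted p = 0.054), which was 0.35 without the 2 arms farthest from the median. Arms are not independent replicates, and the rho lies below the 0.5 that copy number was taken to need on all arms and just above it, at 0.52 (permutation p = 0.0033, adjusted p = 0.0066; r of 0.54, adjusted p = 0.0036), on the 31 arms with at least 5 H3K4me1 regions, a choice made after the first value was seen, so it cannot be told apart from a regional change of the mark. The other pairs of marks were also positively related, with rho of 0.32 (adjusted p = 0.054) and r of 0.39 (adjusted p = 0.022) on all arms and rho of 0.35 (adjusted p = 0.054) and r of 0.48 (adjusted p = 0.010) on the 31 for H3K4me1 with H3K4me3, and rho of 0.60 (adjusted p = 0.00015) and 0.67 (adjusted p = 0.00015), r of 0.54 (adjusted p = 0.0013) and 0.66 (adjusted p = 0.00042), for H3K27ac with H3K4me3.

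Zinc finger promoters with H3K4me3 in parental only, 32 genes with 33 regions, were more than random choice gave, whose highest of 10000 draws was 14. The draws took promoters singly, although 17 of the 33 regions stood in rows of neighbours, so they give too narrow a range. They were also not matched on score, although most parental-only regions had low scores, so a choice among weakly marked promoters was not tested. Complete loss in D4 of the whole segment within 1 Mb would leave none of the other parental regions there with a D4 region. A median of 82.0% of them had one, over 80% in 18 of 32 overlapping windows and under 20% in none. Of the distinct regions, 334 of 365 (91.5%) had a D4 region. These values argue against complete loss of the whole segment in the 32 windows. The share was lowest at ZNF724 and at ZNF91, with 1 of 4 regions, in a row of 5 parental-only regions over 2.04 Mb. Loss of part of a segment, such as this row, or of some copies cannot be told apart from a change of the mark. Short deletions inside the clusters remain open too, as 51.5% of the regions stood in rows of 3 or more neighbours without a D4 region and neither line listed H3K27ac or H3K4me1 in the rows on chromosome 19. A place near the threshold of the parental list is also open, with a median score at percentile 14.8, against 7.40 for the other parental-only promoter regions. Silencing of these clusters in D4 was not tested, since the files hold no values of the input libraries, which would show a deletion.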
